A study of Mus musculus with 12 samples.

How the data were processed

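Total RNA of bone marrow cells was sequenced from 12 recipient mice of 6 transplanted primary T-ALLs, after red cell lysis and Trizol extraction. Per the labels, the recipients were moribund when treated, the strain background was C57BL/6 x 129Sv/Jae F1, libraries were made with a stranded total RNA kit, and paired reads of 100 bp were taken. Each leukemia gave 1 VEH and 1 DEX library, 4 hours after treatment. Groups were taken from the treatment condition in the labels, and pairs from the leukemia code that both titles of a pair share. The replicate is the leukemia (n = 6), and each arm of a leukemia is a single recipient mouse.

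The deposited table holds FPKM made by the authors, on a linear scale with 2 decimals, for 38339 gene identifiers, of which 27663 were above 0 in at least 1 library. The labels name the build mm10 and the tools Bowtie2 (version 2), RSEM and edgeR without their roles, and give neither the annotation version nor any filter. Column sums differed between libraries, so the values are not TPM. The file holds no counts, so no count-based test or counting interval was used here.

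Gene identities, biotypes, lengths and coordinates came from GENCODE M21 on GRCm38 (the same assembly as mm10), matched by Ensembl identifier for 37607 of 38339 genes. There were 17 symbols shared by several identifiers, and 41 tested genes had values identical to those of another gene. Small RNA was the sum of the biotypes for small nuclear, small nucleolar, small Cajal body, micro, miscellaneous, ribosomal and mitochondrial transfer RNA and related classes. Short gene models give high FPKM per fragment, so this share is not a share of fragments.

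Depth was estimated from the most common product of FPKM and length in 918 sparse genes of 400 to 700 bp, read as 1 fragment with an assumed fragment of 150 bp. This gave 11800000, 64200000, 36900000, 19400000, 36400000 and 23600000 fragments in the VEH libraries of leukemias 1 to 6, and 21600000, 15600000, 28700000, 29400000, 20200000 and 19600000 in the DEX libraries. The highest was 5.45 times the lowest. The peak was least sharp for the VEH library of leukemia 2, with 24% of its genes within 0.2 log2.

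Values were analysed as log2(FPKM + 1), with no further scaling. Genes with an FPKM of at least 1 in at least 6 of 12 libraries were tested (12358). A linear model with leukemia as a block and treatment was fitted in limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend; 5 residual and 3.995 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 differences are the moderated SE, and those of FPKM are SD. Differences between leukemias were tested with the F test on the leukemia terms of the same fit. All p-values called adjusted for single genes are from limma.

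There were 35 gene lists, chosen before the data were examined, as were the tests, the rule for named genes and 23 alternative settings. The 34 lists with at least 4 tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists). The list of sex-linked genes had 2 tested members, with 0 past the threshold, and served to check the pairing. With an estimated correlation, 0 lists were higher and 0 lower, so none of the 13 list calls held. In that setting camera also uses at most the 5 residual degrees of freedom, so lists pass less readily even at a low correlation. The glucocorticoid target list, with an estimated correlation of 0.0346, had an adjusted camera p of 0.246 there. The loss of these calls is therefore not due to the correlation alone. Named genes were the 12 largest rises and 10 largest falls among genes past the threshold with a mean of at least 3 FPKM and 1 direction in all 6 leukemias, leaving out gene models without a name and ribosomal pseudogenes. To these came 10 genes fixed by name, up to 4 members of each list with the smallest p, and, between leukemias, the 10 widest ranges and up to 4 members of 4 T-cell lists. Other list members given as examples (Dusp1, Nfkbia, Per1, Mt2, Sgk1, Klf9, Fkbp4, Ptpn22, Isg15, Rtp4, Tcf7, Cdc25c and Atf4) were chosen after their values were seen. The text gives only some of the genes that the rule names, and the others are not reported here.

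The glucocorticoid target response was tested by all 64 sign flips of the 6 within-leukemia means. Relations over the 6 leukemias were tested with Pearson's r and Spearman's rho over all 720 pairings, two-sided, with Benjamini-Hochberg adjustment over 3 relations. The pairing was checked with the values: after removal of group means, the VEH and DEX libraries of a leukemia were correlated across genes at 0.55 to 0.82, and libraries of different leukemias at up to 0.21. Genes are not independent replicates in these correlations. The highest Trbv gene was shared within 6 of 6 pairs.

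The method was tested on simulated data of 12212 genes with the measured spread and noise drawn independently for each gene. It recovered 50% of 66 genes changed by 0.5 log2, 88.9% of 63 changed by 1 and 100% of 65 changed by 2, with 3.14% false calls, and made 0 calls when no gene was changed. In the measured data the estimated correlation within lists reached 0.756 (granulocyte markers), so these rates do not cover correlated genes. Alternatives were other pseudocounts, filters, scalings, variance models, library weights, the block left out or made a random effect, and each leukemia left out in turn. A further 7 settings were chosen after seeing the data: leukemias 1, 3 and 4 alone, leukemias 2, 5 and 6 alone, a term for the 3 DEX libraries described without an index, the set without leukemias 2 and 6, a myeloid marker covariate, protein-coding genes only, and removal of trends with GC content and length. With the term for the 3 DEX libraries, the DEX difference is estimated from leukemias 1, 3 and 4 only. That setting and leukemias 1, 3 and 4 alone are therefore not independent alternatives. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.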

Results

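RNA levels were measured by total RNA sequencing in 12 libraries from 6 primary mouse T-lineage acute lymphoblastic leukemias (T-ALL, a cancer of immature T cells). Each leukemia had been transplanted into recipient mice, and bone marrow was taken from 1 recipient given vehicle (VEH) and 1 given dexamethasone (DEX, a synthetic glucocorticoid), 4 hours after treatment. This gave 6 VEH and 6 DEX libraries in 6 pairs, numbered here as leukemias 1 to 6 (codes 73A-46B, 73M-19A, 78A-143B, 2M-127B, 20M-116B and JW-81-59B). The series title names loss of the glucocorticoid receptor and resistance to dexamethasone in vivo. The labels name no resistant group among these libraries, and the comparison addressed the early transcript response to the drug and its spread over leukemias.

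The deposited values were FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library), and the file gave no counts or depth. FPKM summed to between 1466471 and 2019058 per library, and 11778 to 12970 genes reached an FPKM of at least 1. An estimate from the value of 1 fragment in sparse genes gave 11800000 to 64200000 fragments per library, with a mean of 32100000 ± 18500000 in VEH and 22500000 ± 5460000 in DEX (SD, n = 6 each). Gene models of small RNA held 64.4 ± 1.53% of the summed FPKM in VEH and 67.0 ± 3.39% in DEX (SD, n = 6 each). The 3 highest genes of a library held 32.6% to 42.8% of it.

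After 4 hours of dexamethasone, 9 of 26 glucocorticoid target genes and 3 of 9 pro-death genes of the BCL2 family rose. Myc fell, as did 25 of 40 MYC target and ribosome biogenesis genes, 12 of 21 glycolysis genes and 11 of 23 thymocyte and T-ALL transcription factors. These 5 lists passed the camera test with a preset correlation but not with an estimated one (adjusted p = 0.246 to 0.488 with an estimated correlation). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose from 305 ± 47.9 to 633 ± 78.1 FPKM (SD, n = 6), and Bcl2l11, which encodes the death effector BIM, rose from 20.7 ± 5.32 to 48.1 ± 12.6 FPKM. Myc, a transcription factor that drives growth, fell from 72.5 ± 11.1 to 28.7 ± 5.34 FPKM. Nr3c1, the glucocorticoid receptor gene itself, rose from 56.8 ± 18.3 to 90.5 ± 22.3 FPKM. Each of these 4 genes moved the same way in all 6 leukemias.

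Of 12358 genes tested with limma, 528 were higher and 1147 lower with DEX at an adjusted p under 0.05, and 103 and 41 of them by at least 1 on the log2 scale. The direction was shared by all 6 leukemias for 428 of the higher and 1021 of the lower genes, which a paired test favours when it selects them. Protein-coding genes made up 454 of the higher and 1054 of the lower ones. The split between higher and lower depended on scaling: the median gene stood at -0.05, with 31.5% of the changed genes higher. Median-of-ratios scaling gave 683 higher and 718 lower genes, quantile normalization 651 and 843, and rescaling to TPM (a fixed sum per library) 261 and 1889 at a median of -0.17. Every one of the 1675 calls kept its sign under each alternative in which it was tested. Much of this was fixed by construction, since genes with 1 direction in all 6 leukemias keep it in any set of fewer leukemias. Leaving out the block or changing the variance model also leaves the difference itself as it was.

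Fam69b was among the largest rises and had a low error (ENSMUSG00000036186, GRCm38 chromosome 2, 26628457 to 26636497). It rose from 10.2 ± 1.69 to 79.7 ± 14.8 FPKM (SD, n = 6). Its log2 difference was 2.85 ± 0.13 (SE), with an adjusted p of 2.2e-05. AA467197 (ENSMUSG00000033213, chromosome 2, 122636986 to 122641191) rose by 2.72 ± 0.12, from 19.3 to 138 FPKM (adjusted p = 2.2e-05). Ryr3, a calcium release channel of the endoplasmic reticulum, rose by 2.04 ± 0.35, the collagen chain gene Col27a1 by 2.03 ± 0.30, and Ston1, an endocytic adaptor, by 1.98 ± 0.13. Trnp1 (2.60), Cables1 (1.84), Thnsl2 (1.76), Vwce (1.71) and Sertad4 (1.70) rose as well. The rule that picked these genes and the largest falls required 1 direction in all 6 leukemias. In leukemia 6, Ryr3 (0.09 FPKM in VEH, 0.19 in DEX) and Trio (0.14 and 0.16) were near the floor, so their direction there carries little weight. Snora17, a small nucleolar RNA next to Fam69b on chromosome 2 (26639190 to 26639321), rose by 3.58 ± 0.73 (adjusted p = 0.0153). It was at 0 FPKM in the VEH libraries of leukemias 1, 4 and 6, so the size depends on the pseudocount and is no measured fold, single leukemias ranged from 0.81 to 6.32, and the call was lost in 9 of 25 alternatives. The guanine nucleotide exchange factor gene Trio rose by 1.72 ± 0.38 (adjusted p = 0.0202), a call lost in 6 of 25. Without leukemia 1, Snora17 stood at 3.48 (adjusted p = 0.0508) and Trio at 1.58 (adjusted p = 0.0654), and without leukemia 4 Trio stood at 1.63 (adjusted p = 0.0582).

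Among the 10 largest falls, Art2b, a cell-surface ADP-ribosyltransferase, fell by 1.64 ± 0.29, and the related Art2a-ps fell by 1.69 ± 0.29 (SE, n = 6). In leukemia 6 both were near the floor, at 0.17 and 0.04 FPKM in VEH and 0 in DEX. Id3, an inhibitor of E-protein transcription factors (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755), fell by 1.63 ± 0.16, from 16.6 ± 11.3 to 4.198 ± 2.98 FPKM (adjusted p = 0.00108). Ccr4, a chemokine receptor, fell from 12.9 ± 1.19 to 4.59 ± 1.61 FPKM, and Mthfd2, a mitochondrial enzyme of folate metabolism, from 29.0 ± 3.82 to 11.0 ± 3.06 FPKM. Lipg (-1.58), Clec2d (-1.55), Klf3 (-1.44), Kis2 (-1.39) and Nabp1 (-1.39) fell as well. For genes at a few FPKM, differences of log2(FPKM + 1) understate the fold change.

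**Figure D1:**
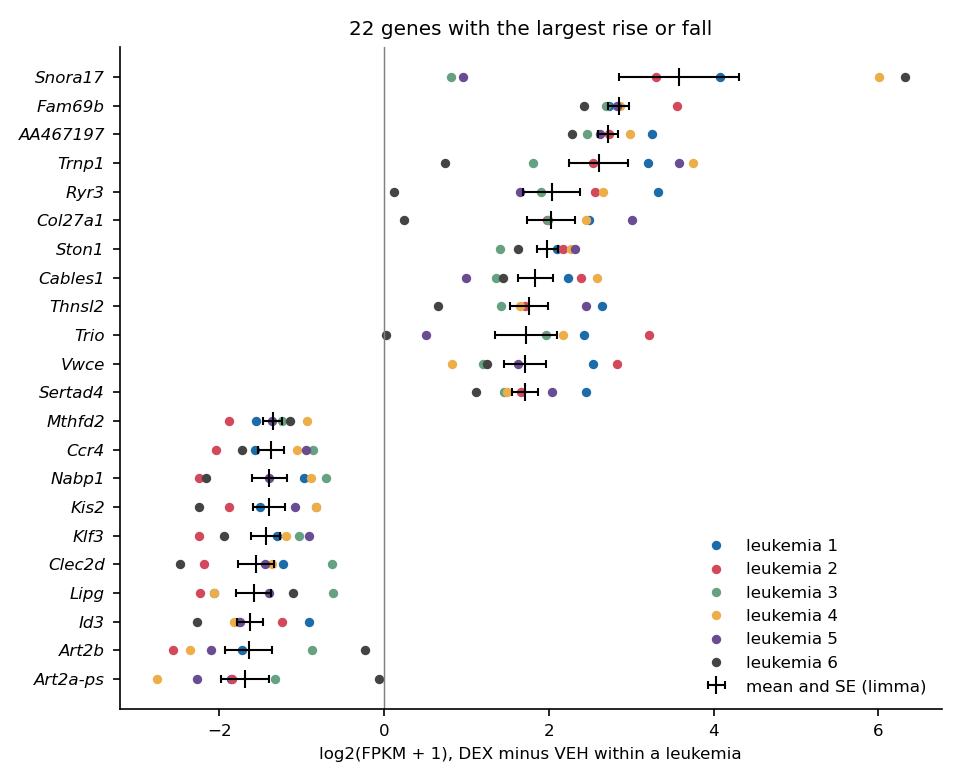
The horizontal axis is the difference in log2(FPKM + 1), DEX minus VEH, and each row is 1 of the 22 genes with the largest rise or fall; dots are the 6 leukemias and black marks the mean with its SE. The genes were picked for having 1 direction in all 6 leukemias, and Col27a1 in leukemia 6 (0.24) lies apart from its other values (1.98 to 3.01). In leukemia 6, Ryr3 (0.13), Trio (0.03), Art2b (-0.23) and Art2a-ps (-0.06) rest on values under 1 FPKM.

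Of 26 tested members of the glucocorticoid-induced target list, 9 rose, 0 fell and 17 did not pass, and 11 rose and 1 fell when adjusted over the list alone. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), rose by 1.38 ± 0.19 (SE, n = 6), from 43.6 to 116.2 FPKM. Ddit4, an inhibitor of mTORC1, rose by 1.69 ± 0.15, Txnip, a thioredoxin-binding inhibitor of glucose uptake, by 1.51 ± 0.13, and the phosphatase gene Dusp1 by 1.04. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) rose by 1.06 ± 0.12 (adjusted p = 0.00179). Per1 (0.87, adjusted p = 0.18), Mt2 (0.74, adjusted p = 0.074) and Sgk1 (0.05) did not pass, and Klf9, at 0.17 FPKM in VEH and 0.59 in DEX, was too low to be tested. The list was higher than other genes (camera adjusted p = 1.1e-06, median 0.32), which did not hold with an estimated correlation (adjusted p = 0.246 with an estimated correlation). The mean difference over the list, called the glucocorticoid target response here, was 0.42 ± 0.15 (SD, n = 6) and lay between 0.22 and 0.64 in single leukemias (exact two-sided sign-flip p = 0.03125, the smallest that 6 pairs allow). Rescaled to TPM it was 0.32 (exact p = 0.0625). Without Il7r, Txnip, Btg1, Irs2 and Cdkn1a it was 0.45 over 21 genes, which still included Ddit4, Pik3ip1 and Sesn1, members of other lists too.

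Nr3c1 (ENSMUSG00000024431, chromosome 18, 39410545 to 39519421) rose by 0.69 ± 0.08 (SE, n = 6; adjusted p = 0.00163), and its VEH level ranged from 35.6 FPKM in leukemia 6 to 81.9 FPKM in leukemia 4. The list of the receptor with its chaperones and cofactors had 1 member that rose, 5 that fell and 19 that did not pass of 25, and 3 and 7 when adjusted over the list alone. The falls included the chaperone Hsp90aa1 (-0.52), the immunophilin Fkbp4 (-0.49) and Hsd11b1 (-0.68), an enzyme that activates glucocorticoids. The list did not pass the camera test (adjusted p = 0.416, median -0.11).

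In the pro-apoptotic BCL2 family, 3 of 9 tested members rose, 0 fell and 6 did not pass, with the same counts of 3 and 0 when adjusted over the list alone. Bcl2l11 (ENSMUSG00000027381, chromosome 2, 128126038 to 128162547) rose by 1.18 ± 0.17 (SE, n = 6, adjusted p = 0.00473), Bmf by 1.48 ± 0.13 and Bbc3, which encodes PUMA, by 1.49 ± 0.27, each in 6 of 6 leukemias. In leukemia 1, however, Bbc3 hardly changed (6.12 to 6.48 FPKM, 0.07 on the log2 scale), against rises of 0.96 to 2.485 in the others. The list passed camera (adjusted p = 0.0343, median 0.06; adjusted p = 0.488 with an estimated correlation) but the call was lost in 10 of 25 alternatives. These included the set without leukemia 6 (median 0.01, adjusted p = 0.102), leukemias 1, 3 and 4 alone (adjusted p = 0.271), the term for the index (adjusted p = 0.154) and no filter (adjusted p = 0.219), and the median was -0.05 when rescaled to TPM. Of 10 anti-apoptotic genes and inhibitors of apoptosis, 1 rose, 1 fell and 8 did not pass, and 2 rose and 1 fell when adjusted over the list alone. Cflar, an inhibitor of caspase-8, fell by 0.40, and Bcl2 (0.02 ± 0.09, adjusted p = 0.92) and Mcl1 (0.15 ± 0.09, adjusted p = 0.26) did not pass. That list did not pass camera (adjusted p = 0.502), where its test pointed up while its median (-0.05) and mean (-0.02) were below 0.

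**Figure D2:**
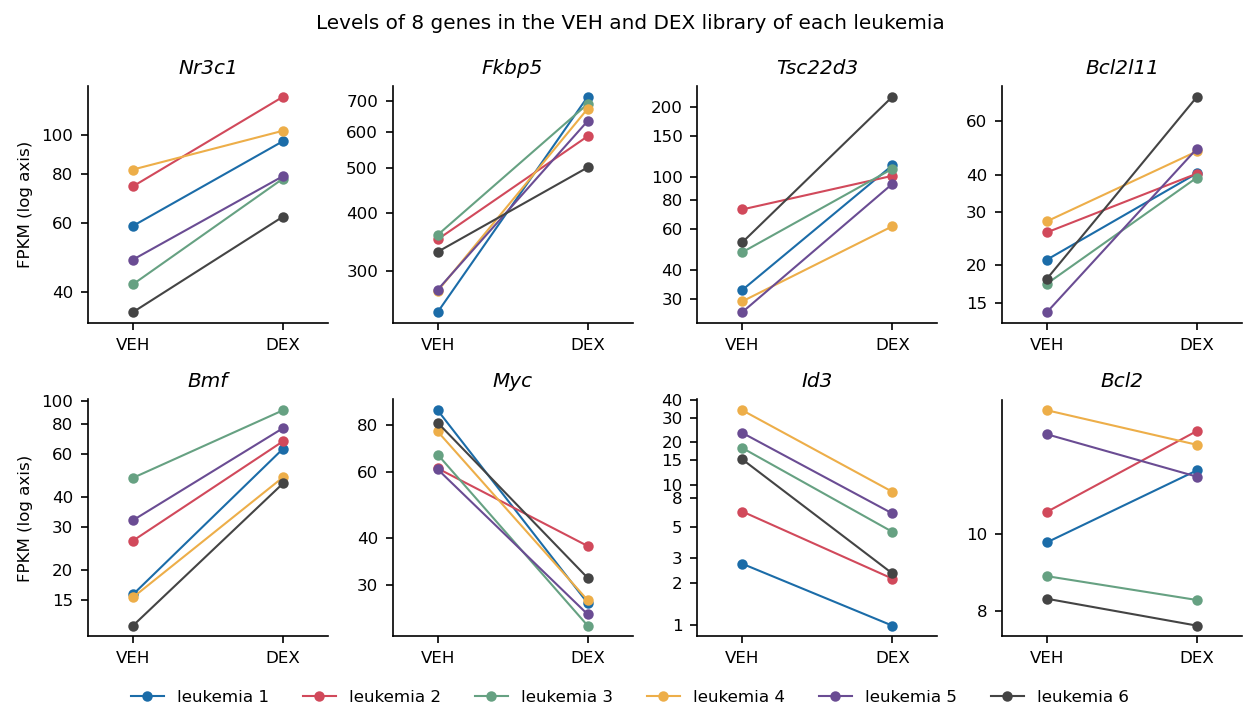
The vertical axes are FPKM on log axes for 8 genes, and each line joins the VEH and DEX library of 1 of the 6 leukemias. The lines of Myc all run down (mean 72.5 to 28.7 FPKM), and those of Fkbp5, Tsc22d3, Nr3c1 and Bcl2l11 all run up.

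Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) fell by 1.31 ± 0.12 (SE, n = 6; adjusted p = 0.000651), and MYC targets and ribosome biogenesis genes form the next list. Of its 40 members, 0 rose, 25 fell and 15 did not pass, and 30 fell when adjusted over the list alone. Gnl3, a nucleolar GTPase, fell by 0.96, the RNA methyltransferase gene Nop2 by 0.72, Polr1b, a subunit of RNA polymerase I, by 0.71, and Dkc1, a pseudouridine synthase, by 0.60. The list was lower in 6 of 6 leukemias (camera adjusted p = 4.3e-11, median -0.38; adjusted p = 0.488 with an estimated correlation).

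Of 30 S phase and DNA replication genes, 0 rose, 11 fell and 19 did not pass, and 13 fell when adjusted over the list alone. They included the helicase subunit Mcm4 (-0.54) and the replication licensing factor Cdc6 (-0.62), whose call ended without leukemia 5 (-0.57, adjusted p = 0.0559). That list was lower (camera adjusted p = 0.000288, median -0.25; adjusted p = 0.562 with an estimated correlation). Of 30 G2 and M phase genes, 9 rose, 0 fell and 21 did not pass, with the same 9 when adjusted over the list alone. Ccnb2, a mitotic cyclin, rose by 0.44, the centromeric histone gene Cenpa by 0.40 and Cdc25c, a phosphatase of mitotic entry, by 0.53. The G2 and M list was higher (camera adjusted p = 4.2e-08, median 0.24; adjusted p = 0.532 with an estimated correlation), with a mean above 0 in leukemias 1, 3, 4 and 5 and below 0 in leukemia 2 (-0.17) and leukemia 6 (-0.10). The S phase mean was below 0 in these as well (-0.41 and -0.10), and the difference between the lists was not tested. Leukemias 2 and 6 also had the lowest means of the granulocyte markers (-1.20 and -1.09). Among 15 cyclins, kinases and their inhibitors, 2 rose, 3 fell and 10 did not pass (2 and 5 when adjusted over the list alone; camera adjusted p = 0.414, median -0.21). Ccnd3, a G1 cyclin, fell by 0.66, a call that ended without leukemia 5 (-0.64, adjusted p = 0.0524), and Cdkn1a did not pass (-0.28 at 2.08 FPKM in VEH, adjusted p = 0.28).

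**Figure D3:**
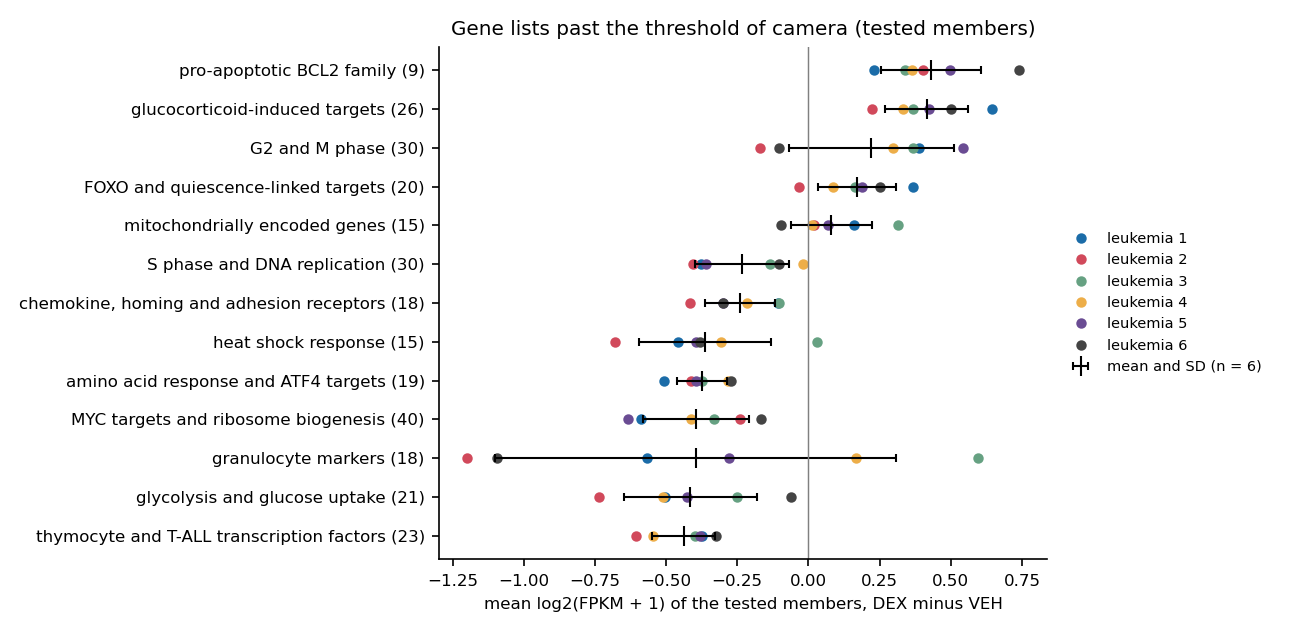
The horizontal axis is the mean difference in log2(FPKM + 1) of a list's tested members, DEX minus VEH; dots are the 6 leukemias and black marks the mean with its SD. The 5 higher and 8 lower lists past the camera threshold are shown, and the granulocyte marker list has the widest spread (-1.20 to 0.60).

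Among 23 thymocyte and T-ALL transcription factors, 1 rose, 11 fell and 11 did not pass, and 1 rose and 12 fell when adjusted over the list alone. Gata3, a regulator of early T-cell development, fell by 1.13, from 19.2 to 7.80 FPKM, Ikzf2 by 1.26, Tox by 0.72 and Tcf7 by 0.68. The list was lower in 6 of 6 leukemias (camera adjusted p = 8.5e-05, median -0.39; adjusted p = 0.453 with an estimated correlation). In the list of the T-cell receptor complex and its signalling, 4 of 28 members rose, 10 fell and 14 did not pass, and 6 rose and 12 fell when adjusted over the list alone (camera adjusted p = 0.241, median -0.15). Cd5 fell by 0.82 and the adaptor gene Lcp2 by 0.50, while the inhibitory genes Ubash3a and Ptpn22 rose by 0.84 and 0.70. Of 12 RAG recombination and pre-TCR genes, 1 rose, 2 fell and 9 did not pass, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.829, median -0.09). Dntt, a template-independent DNA polymerase, fell by 0.70, and Rag1 did not pass (-0.53, adjusted p = 0.055).

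Notch1 stood at 203 FPKM in VEH and 198 FPKM in DEX (log2 difference -0.02, adjusted p = 0.90). Of 13 NOTCH1 targets, 0 rose, 2 fell and 11 did not pass, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.157, median -0.23). The 2 that fell were Myc and Il2ra, the alpha chain of the interleukin 2 receptor, which fell by 1.04, from 141 to 66.1 FPKM. Of 22 genes of IL7 receptor, JAK and STAT signalling, 2 rose, 4 fell and 16 did not pass, and 3 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.147, median -0.20). Il7r itself did not pass (0.07, adjusted p = 0.82), and the kinase gene Pim3 fell by 0.55.

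Of 20 FOXO and quiescence-linked genes, 4 rose, 1 fell and 15 did not pass, with the same 4 and 1 when adjusted over the list alone. Txnip (1.51), Pik3ip1 (0.79), an inhibitor of PI3K, and Sesn1 (0.52) rose. The list was higher (camera adjusted p = 0.00334, median 0.11; adjusted p = 0.488 with an estimated correlation), and the call ended when leukemias 2, 5 and 6 were taken alone (median 0.07, adjusted p = 0.0828). In the PI3K, AKT and mTOR list, 6 of 25 members rose, 3 fell and 16 did not pass, and 7 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0708, median 0.01). Pik3r1, a regulatory subunit of PI3K, rose by 1.07 and Pik3cd, a catalytic subunit, fell by 0.45.

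Of 21 glycolysis and glucose uptake genes, 0 rose, 12 fell and 9 did not pass, and 16 fell when adjusted over the list alone. Hk2, which encodes a hexokinase, fell by 0.93, the lactate transporter gene Slc16a1 by 0.80, Pfkfb3, a regulator of phosphofructokinase, by 0.67 and the glucose transporter gene Slc2a3 by 0.51. The list was lower in 6 of 6 leukemias (camera adjusted p = 7.4e-06, median -0.45; adjusted p = 0.488 with an estimated correlation). Of 19 amino acid response and ATF4 targets, 1 rose, 9 fell and 9 did not pass, and 1 rose and 10 fell when adjusted over the list alone. Mthfd2 fell by 1.35, the arginine transporter gene Slc7a1 by 1.11, Slc38a2, a neutral amino acid transporter, by 0.81, and Atf4 by 0.46, while the cystine transporter gene Slc7a11 rose by 1.03. That list was lower (camera adjusted p = 0.000118, median -0.32; adjusted p = 0.488 with an estimated correlation). Of 29 cholesterol and fatty acid synthesis genes, 0 rose, 4 fell and 25 did not pass, also when adjusted over the list alone (camera adjusted p = 0.266, median -0.11), among them Fasn, the fatty acid synthase gene, which fell by 0.51.

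Of 15 heat shock response genes, 0 rose, 8 fell and 7 did not pass, and 12 fell when adjusted over the list alone. The mitochondrial chaperone gene Hspd1 fell by 0.71 and Hsf1, the main transcription factor of the heat shock response, by 0.40 (camera adjusted p = 0.000281, median -0.37; adjusted p = 0.488 with an estimated correlation). Leukemia 3 had a list mean of 0.03. Of 20 endoplasmic reticulum chaperones and related genes, 1 rose, 2 fell and 17 did not pass, also when adjusted over the list alone (camera adjusted p = 0.416, median -0.10). Herpud1, a component of protein degradation at the endoplasmic reticulum, rose by 1.05. Of 16 p53 targets, 1 rose, 1 fell and 14 did not pass, and 2 rose and 1 fell when adjusted over the list alone. Bbc3 rose and Trp53 itself fell by 0.36. The p53 list did not pass camera (adjusted p = 0.872), and its test and mean (0.03) pointed up while its median (-0.09) was below 0. All 15 mitochondrially encoded genes failed to pass singly, also when adjusted over the list alone. As a list they passed camera upward (adjusted p = 0.0239, median 0.05; adjusted p = 0.599 with an estimated correlation), but not without leukemia 1 (median 0.04, adjusted p = 0.0517) or leukemia 3 (median 0.03, adjusted p = 0.169), nor rescaled to TPM, and the median was -0.05 after quantile normalization.

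Of 14 NF-kappaB and inflammatory genes, 1 rose, 3 fell and 10 did not pass, and 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.0775, median -0.22). Tnf, a cytokine gene, fell by 0.74, and Nfkbia, an inhibitor of NF-kappaB counted in the glucocorticoid list, rose by 0.67. Among 22 interferon-stimulated genes, 3 rose, 3 fell and 16 did not pass, and 3 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.266, median -0.18). Usp18 rose by 1.38, Mx2 by 1.17 and Ifi35 by 0.57, while Oas2 fell by 0.62, Isg15 by 0.47 and Rtp4 by 0.46. The call of Oas2 ended without leukemia 3, 4 or 5, at -0.63, -0.60 and -0.66. Of 20 immediate-early and MAPK feedback genes, 2 rose, 3 fell and 15 did not pass, also when adjusted over the list alone (camera adjusted p = 0.903, median -0.06), and the phosphatase gene Dusp4 fell by 0.65. In the circadian list, 1 of 12 rose, 2 fell and 9 did not pass, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.832, median -0.05). Dbp, a clock output gene, fell by 0.47, a call that ended without leukemia 1 (-0.48, adjusted p = 0.0554). Of 18 chemokine, homing and adhesion receptors, 0 rose, 7 fell and 11 did not pass, and 8 fell when adjusted over the list alone, with Ccr4 (-1.37) and the integrin gene Itgb1 (-0.37) among them. That list passed camera (adjusted p = 0.0444, median -0.29; adjusted p = 0.488 with an estimated correlation) but not without leukemia 2 (median -0.22, adjusted p = 0.0758), 4 (-0.31, 0.0521), 5 (-0.27, 0.0603) or 6 (-0.25, 0.07), and was lost in 13 of 25 alternatives.

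Markers of other bone marrow cells were measured beside these groups. Of 18 granulocyte markers, 0 rose, 1 fell and 17 did not pass, and 0 passed when adjusted over the list alone. The one that fell was Ltf, the lactoferrin gene (-0.91, adjusted p = 0.034), whose call ended without leukemia 1, 2, 4, 5 or 6, at -0.90, -0.69, -0.99, -0.91 and -0.82. S100a9 did not pass (-0.62, adjusted p = 0.11). The list mean was -0.57, -1.20, 0.60, 0.17, -0.28 and -1.09 in leukemias 1 to 6, and the list passed camera downward (adjusted p = 0.0444, median -0.44; adjusted p = 0.733 with an estimated correlation), but not without leukemia 1 (median -0.40, adjusted p = 0.119), 2 (-0.31, 0.199) or 6 (-0.26, 0.218). That call was lost in 12 of 25 alternatives, and the direction of the camera test turned in 2 more. Those 2, leukemias 1, 3 and 4 alone and the term for the index, rest on the same DEX differences. Of 11 monocyte, macrophage and dendritic cell markers, 1 rose (Flt3, a growth factor receptor of progenitors, by 0.46), 0 fell and 10 did not pass, also when adjusted over the list alone. Flt3 did not pass without leukemia 1, 4 or 5, at 0.49, 0.45 and 0.49. For the monocyte list camera pointed up (adjusted p = 0.649), with a median of 0.01 and a mean of -0.09.

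Of 8 erythroid markers, 0 rose, 1 fell and 7 did not pass, and 2 fell when adjusted over the list alone (camera adjusted p = 0.148, median -0.54). The one that fell was Tfrc, the transferrin receptor gene. Its call was lost in 18 of 26 alternatives, among them each leukemia left out in turn. Hbb-bt, Alas2 and Hemgn did not pass. The list mean was -2.53 in leukemia 2 and -1.42 in leukemia 1, and between -0.19 and 0.36 in the others. Of 8 B-lymphoid and plasma cell markers, 0 rose, 1 fell (Sdc1, a plasma cell proteoglycan, by 0.64) and 7 did not pass, also when adjusted over the list alone (camera adjusted p = 0.148, median -0.42). Of 4 natural killer cell markers 0 passed, and 2 fell when adjusted over the list alone (camera adjusted p = 0.213, median -0.30). None of 6 megakaryocyte and platelet markers passed in either count (camera adjusted p = 0.414, median 0.02). Of 5 stromal and endothelial markers, 1 rose, 1 fell and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 0.437, median 0.04). With the mean level of the granulocyte and monocyte markers as a covariate, 368 genes were higher and 757 lower with DEX, and 331 and 697 of them were among the calls above.

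The small RNA share was higher by 6.6, 4.78 and 5.09 percentage points in the DEX libraries of leukemias 2, 5 and 6, and changed by 0.66, -1.06 and -0.58 points in leukemias 1, 3 and 4. The same 3 DEX libraries were described without the index suffix that ends the description of the other 9. Taken alone, leukemias 1, 3 and 4 gave 399 higher and 525 lower genes, of which 265 and 406 were shared with the calls over all 6. Leukemias 2, 5 and 6 gave 270 and 275, of which 123 and 212 were shared. With a term for the 3 libraries, 236 genes were higher and 282 lower, and the term itself passed for 6 genes (limma, with 1580 at an unadjusted p under 0.05). With this term the DEX difference of a gene is that of leukemias 1, 3 and 4, and only the spread comes from all 6. It is therefore no independent check beside leukemias 1, 3 and 4 alone. The glucocorticoid target response was 0.40 in each of these sets of 3 leukemias (exact sign-flip p = 0.25, the smallest that 3 pairs allow). The filter was applied anew within each set, so these means are over different list members. Over the 26 genes tested in all 6 leukemias it was 0.64, 0.37 and 0.33 in leukemias 1, 3 and 4. In leukemias 2, 5 and 6 it was 0.22, 0.42 and 0.50. Without the leukemia block, 35 genes were higher and 46 lower (1469 at an unadjusted p under 0.05), all of them among the calls with the block. Leaving out leukemia 1 gave 266 and 486, leukemia 2 361 and 753, leukemia 4 282 and 584, and leukemia 5 234 and 420.

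The leukemias differed from each other more than DEX and VEH did. Leukemia accounted for 77.1% of the variance of the tested genes and treatment for 10.9%, and 6321 genes (51.1%) differed between leukemias at an adjusted p under 0.05 (limma F test), of which 1056 also changed with DEX. The leukemia terms use 5 degrees of freedom and treatment 1, so neither these shares nor the counts of genes are like measures. Genes of the T-cell receptor held several of the widest ranges. Trbc1, a constant region of the receptor beta chain, was at 1813 FPKM in the VEH library of leukemia 5, and at 0.63 and 0.46 FPKM in leukemias 2 and 3 (range 10.54 on the log2 scale, adjusted p = 4.2e-09). Trbv19 was the highest beta variable gene in leukemias 1, 4 and 5, Trbv13-1 in leukemia 2, Trbv26 in leukemia 3 and Trbv5 in leukemia 6, in VEH and in DEX alike, with 55% to 94.2% of the summed Trbv signal. Trbv12-1 was at 251 FPKM in the VEH library of leukemia 6 and at most 5.71 FPKM in those of the others.

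Several lineage genes set leukemia 6 apart, as given by the VEH libraries. Cd8a, a co-receptor gene, was at 0.5 FPKM in its VEH library against 36.9 to 195 FPKM in the others, and Cd4 at 3.48 against 8.04 to 182.6 FPKM. The NOTCH1 target Heyl was at 1.56 FPKM there against 18.6 to 27.8 FPKM. Spib, a transcription factor of B and dendritic cells that the B-lymphoid list also holds, was at 265 FPKM in leukemia 6 and at most 11.2 FPKM elsewhere. Of the receptor gamma chain genes, Tcrg-V7 was at 331 FPKM in leukemia 6 and at most 8.52 elsewhere, Tcrg-C1 ranged from 0.89 to 799 FPKM and Tcrg-C2 from 0.31 to 559 FPKM. Il7r, the interleukin 7 receptor gene, was at 0.25 and 0.8 FPKM in leukemias 5 and 6 and at 10.8 to 39.0 FPKM in the others. Lmo1, a T-ALL oncogene, was at 0.71 FPKM in leukemia 1 and 2.31 in leukemia 6, and at 12.8 to 18.4 FPKM in the rest. Xrcc5, a subunit of the Ku DNA repair complex, was at 105 FPKM in leukemia 4 and at most 28.0 elsewhere. Cym ranged from 0.37 to 132 FPKM in VEH and rose with DEX by 1.65 (adjusted p = 0.00473). Xist, expressed in female cells, was at 0.12 FPKM in leukemia 2 and at 98.0 to 355 FPKM in the others, with the Y-linked Ddx3y at 26.8 FPKM in leukemia 2. The Y-linked Eif2s3y was among the tested genes, so it reached 1 FPKM in at least 6 of 12 libraries, not in leukemia 2 alone. The source of this signal was not tested. In leukemias 1, 3 and 4 taken alone 5077 genes differed, and in leukemias 2, 5 and 6 taken alone 3787.

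**Figure D4:**
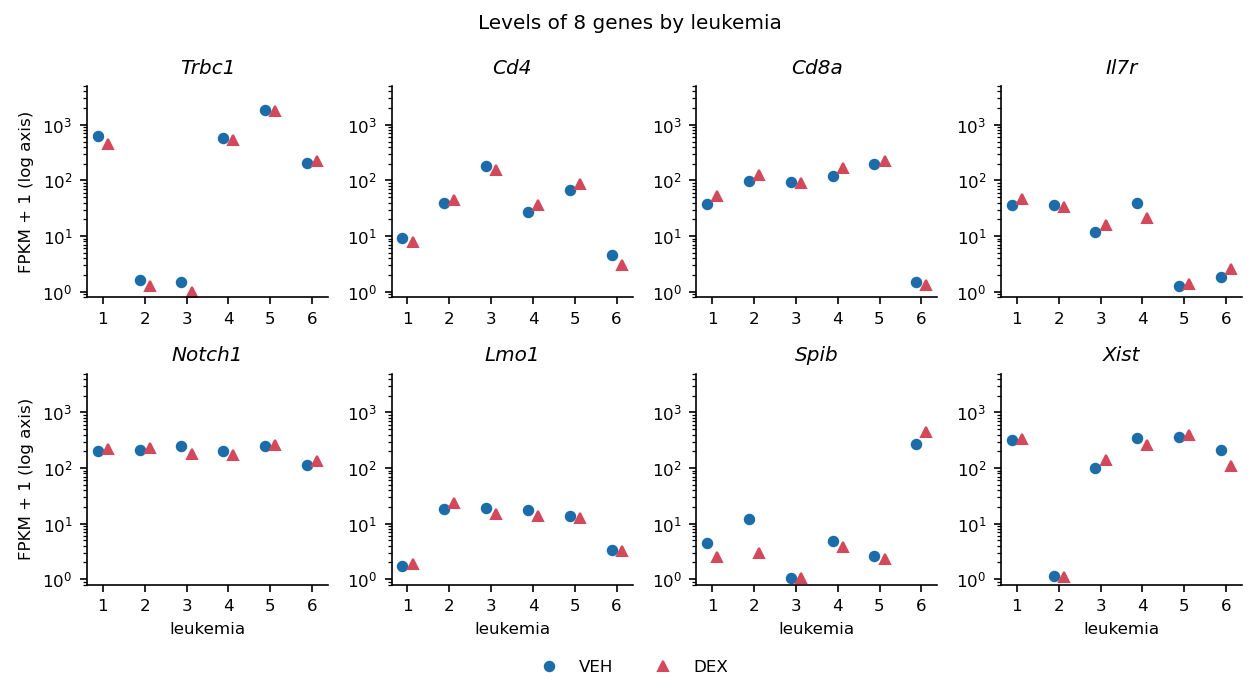
The vertical axes are FPKM + 1 on log axes for 8 genes, and the horizontal axes are the 6 leukemias, with VEH as circles and DEX as triangles. The VEH and DEX values of a leukemia lie close together beside the ranges between leukemias, as for Trbc1 (0.46 to 1813 FPKM in VEH) and Spib (265 FPKM in leukemia 6).

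The relation of receptor level to response was examined over the 6 leukemias in 3 relations fixed in advance. The VEH level of Nr3c1 went with the glucocorticoid target response at r = -0.42 (exact permutation p = 0.417, adjusted p = 0.417) and rho = -0.54 (exact permutation p = 0.297, adjusted p = 0.297). Without leukemias 4 and 6, the farthest from the median, r was -0.23, and with only genes of at least 5 FPKM in 6 libraries it was 0.25. The same level went with the rise of Bcl2l11 at r = -0.85 (exact permutation p = 0.0458, adjusted p = 0.138) and rho = -0.89 (exact permutation p = 0.0333, adjusted p = 0.1), and r was -0.69 without leukemias 4 and 6. This relation did not pass after adjustment. Its unadjusted exact p was 0.0542 with median-of-ratios scaling and 0.0722 with quantile normalization. The glucocorticoid target response went with the change of Myc at r = -0.75 (exact permutation p = 0.104, adjusted p = 0.156) and rho = -0.54 (exact permutation p = 0.297, adjusted p = 0.297). It was 0.66 without leukemias 1 and 2, so the sign rested on those leukemias. The libraries with and without an index suffix part the leukemias into sets of 3, too few for a correlation within either.

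**Figure D5:**
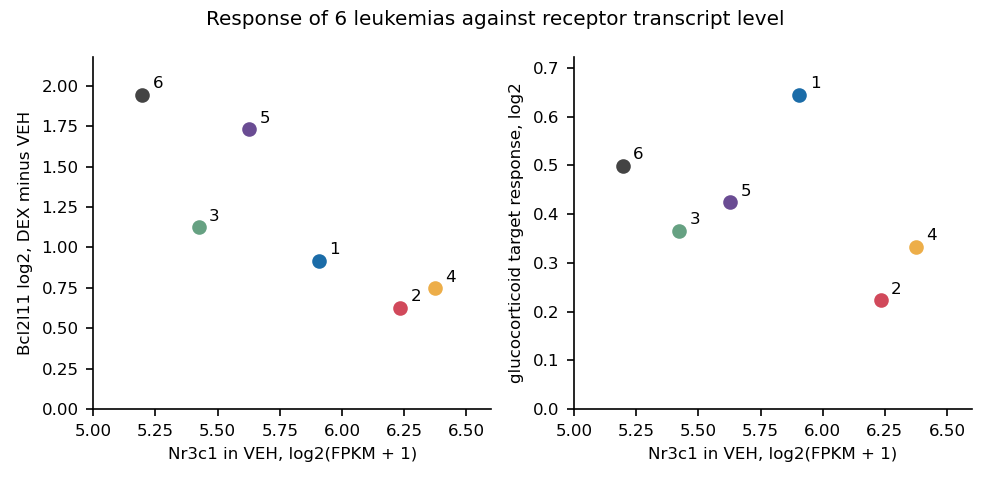
The horizontal axes are the VEH level of Nr3c1 in log2(FPKM + 1), and the vertical axes are the glucocorticoid target response and the rise of Bcl2l11, both in log2(FPKM + 1), with 1 point per leukemia. The rise of Bcl2l11 was 1.94 in leukemia 6, with the lowest receptor level, and 0.75 in leukemia 4, with the highest.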

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

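The tests of the small RNA share, of the granulocyte markers and of scaling for Bcl2l11 were chosen only after the result was seen. Counts over other splits of the libraries and the remaining tests of Bcl2l11 were fixed before.

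A search of 78 groups of 6 values for a sample far from the other 5 picked out 5, where chance picks out about 1 in 20. The rise of Col27a1 was 0.2442 in leukemia 6, against 1.98 to 3.01 in the others. That of Nr3c1 was 0.3228 in leukemia 4, which had the highest VEH level, against 0.69 to 0.87. The mean of the PI3K, AKT and mTOR list was 0.315 in leukemia 1, against 0.07 to 0.15. The mean of the B-lymphoid and plasma cell markers was -1.585 in leukemia 2, against -0.42 to 0.12. Protein-coding genes held 32.36% of the FPKM in the VEH library of leukemia 1, against 29.08% to 30.21% in the other VEH libraries.

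Chance as the source of the gene counts was argued against, but not excluded, by other splits of the 12 libraries. The real split gave 528 higher and 1147 lower genes and was the only 1 of 100 splits (drawn from 462) with as many, the highest other being 526. Of 32 splits that part every pair, as the real one does, only 1 gave as many, and the highest other gave 0. A share of 1 in 32 is the smallest that these splits allow. Most of the drawn splits leave some pairs whole and fit the contrast on fewer pairs, so they are no like comparison. Among them, 1 split parted no pair, had no fit and was counted as 0. The 2 splits with 526 genes parted only leukemias 2 and 6 between the groups, each with its true treatment. Other drawn splits that parted only 2 leukemias, each with its true treatment, gave 0 genes. Holding the true treatment therefore does not by itself account for the 526, and what sets leukemias 2 and 6 apart here was not tested. For the number of lists chance was not argued against. Of 100 splits, 58 gave 5 or more lists in a direction and 17 gave 8 or more (highest other 13). Among splits that part every pair 15 and 6 of 32 did (highest other 12).

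The small RNA share was higher in the DEX libraries of leukemias 2, 5 and 6. The highest change in leukemias 1, 3 and 4 was 0.66 points, below the lowest of the other 3 at 4.78. This contrast is the pattern itself, so it cannot decide on an effect of DEX common to all leukemias. An exact permutation test of the difference between these sets of 3 gave p = 0.1, the smallest that 20 splits allow. By class, summed small nucleolar RNA was higher with DEX in 6 of 6 leukemias, small nuclear RNA in 5 and miscellaneous RNA in 4. A batch of the 3 libraries described without an index remains a candidate explanation that was not put to a test: the difference in change, 5.817 points, is the pattern itself and gives it no support. It cannot be told apart from a response of these 3 leukemias, since the 3 libraries are all DEX. The biological difference between the leukemias was not tested apart from this.

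Granulocyte markers were lower in the DEX libraries of leukemias 1, 2, 5 and 6. Fewer cells of every other type in the DEX library may account for this in leukemias 1 and 2, and it stays open: 13 of 14 marker list means were below 0, and the highest was 0.1891 ± 0.318 (SE over 5 members), for stromal and endothelial markers in leukemia 2. In leukemias 5 and 6 it stays open too, though more means were above 0. Erythroid markers stood at 0.31 and 0.361 (median VEH levels of 1.36 and 2.09 FPKM), and megakaryocyte and platelet markers at 0.01 and 0.08. The 5 stromal and endothelial markers stood at 0.23 ± 0.11 in leukemia 6, about 2 SE above 0. The bound was changed from 2 SE to a t quantile, and marker lists were added, after the result was seen. Under the first bound, those 5 markers alone would have argued against this explanation in leukemias 5 and 6. An effect of DEX common to all leukemias was left open by the exact sign-flip p of 0.25, with granulocyte means of 0.60 and 0.17 in leukemias 3 and 4. The labels give no sort that would remove granulocytes, and the red cell lysis they name removes erythroid cells to a degree that may differ between libraries and was not measured.

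Bcl2l11 rose less in leukemias with more Nr3c1, a relation that did not pass adjustment. Scaling is argued against, since the r nearest to 0 under the 3 other scalings was -0.8085. A higher starting level of Bcl2l11 in leukemias with more Nr3c1 may account for it: the VEH level of Bcl2l11 went with its rise at r = -0.806 (exact permutation p = 0.0639, adjusted p = 0.0958; rho = -0.77; -0.73 without the 2 farthest) and with that of Nr3c1 at r = 0.81 (exact permutation p = 0.0597), though the VEH level enters the rise with a minus sign. A larger response of all glucocorticoid targets in leukemias with less Nr3c1 stays open, with r = 0.391 between that response and the rise of Bcl2l11 (exact permutation p = 0.444; rho = 0.66; r = 0.96 without the 2 farthest). The leukemias differ in origin, and such biological differences were not tested.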

How the results depend on the processing

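Of the alternatives, 7 were chosen after seeing the data, from leukemias 1, 3 and 4 alone to the removal of GC and length trends as listed with the methods, and the others were planned. All 115 named genes past the threshold kept their sign under every alternative that tested them, which was in large part fixed by construction, as for all calls. Of these genes, 16 also stayed past the threshold under every alternative, 39 under all but no block and no filter, and 20 with no block. The lists of glucocorticoid targets, MYC targets, S phase, G2 and M phase, T-ALL factors, glycolysis, ATF4 targets and heat shock kept their call under all 25 settings of the model. Camera was not run with leukemia as a random effect.

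With no filter, more genes shared the adjustment: 181 genes were higher and 370 lower, and 20 lists lower, whose cause was not tested. Without the block, 35 were higher and 46 lower. Rescaled to TPM, 261 were higher and 1889 lower, and the glucocorticoid response was 0.316. This setting divides by the summed FPKM, with a mean of 1598214 in VEH and 1766130 in DEX. The sum was higher with DEX in leukemias 2, 4, 5 and 6 and lower in leukemias 1 and 3. A higher sum lowers all values of a library by construction. Median-of-ratios scaling gave 718 lower genes and an r of Nr3c1 with Bcl2l11 of -0.8266. This scaling brings the median gene near 0 by construction (0.00097, against -0.053 without it), which shifts the split between higher and lower genes. Quantile normalization gave 3 higher lists, a mitochondrial median of -0.0537 and -0.8085 for that r. Array weights gave 820 higher and 1662 lower genes. With GC and length trends removed, 845 genes were higher and 902 lower, and 3 lists were higher. With the myeloid covariate, 757 genes were lower. With a term for the index, 236 were higher and 282 lower, and the granulocyte median was -0.0424. This median is that of leukemias 1, 3 and 4 alone, since the term leaves the DEX difference to them. Apart from the filter, the rescaling to TPM, the median gene under median-of-ratios scaling and the granulocyte median under the index term, the cause was not tested. With a required change of 1 log2, 103 were higher and 41 lower, by construction. With an estimated correlation 0 lists were higher and 0 lower, where camera also uses at most the 5 residual degrees of freedom. With genes of at least 5 FPKM, the r of Nr3c1 with the glucocorticoid response was 0.2537, and the cause was not tested.

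Sets of fewer leukemias gave fewer or more calls, and apart from their size the cause was not tested. Without leukemias 2 and 6, 687 genes were higher and 1140 lower. Leukemias 1, 3 and 4 alone gave 525 lower genes, 11 lower lists and a granulocyte median of -0.0424. Leukemias 2, 5 and 6 alone gave 270 higher and 275 lower genes, 3 higher lists and 3787 genes differing between leukemias. Leaving out 1 leukemia at a time gave 234 to 537 higher genes and 420 to 1035 lower genes. Without leukemia 1 these were 266 and 486, without 2 361 and 753, without 4 282 and 584, and without 5 234 and 420. Lists were 4 to 6 higher and 7 to 9 lower, and genes differing between leukemias 4666 to 6682. The glucocorticoid response, over the list members tested in each set, was 0.387 to 0.448. The r of Nr3c1 with that response was -0.809 to -0.170, that of Nr3c1 with Bcl2l11 -0.943 to -0.728, and that of the response with Myc -0.858 to -0.508. Without the 2 farthest leukemias the last was 0.6579. Estimated depth differed by 5.45 times between libraries, which limits genes at a few FPKM most.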

Other observations

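The groups of genes below were all chosen after their values were seen, and are given without explanation. Il10, a cytokine gene of the NF-kappaB list too low to be tested, was higher with DEX in 6 of 6 leukemias, from 2.76 to 23.2 FPKM in leukemia 5, 0.48 to 19.7 in leukemia 2, 0.21 to 6.3 in leukemia 6 and 0.14 to 0.23 in leukemia 1. It reached 1 FPKM in 5 libraries. Summed FPKM of 1525 small nucleolar RNA genes was higher with DEX in 6 of 6 leukemias, by 0.49 ± 0.40 on the log2 scale (SD, n = 6; exact sign-flip p = 0.03125, the smallest possible). The difference was 0.90, 0.74 and 0.90 in leukemias 2, 5 and 6, whose DEX libraries lack the index suffix, and 0.08, 0.31 and 0.04 in leukemias 1, 3 and 4. Small nuclear RNA genes (1382) differed by 0.37 ± 0.28 (exact p = 0.0625), with 0.46, 0.62 and 0.68 in leukemias 2, 5 and 6 and -0.08, 0.24 and 0.32 in leukemias 1, 3 and 4. Miscellaneous RNA genes (562), with the highest sum among these classes, differed by 0.06 ± 0.20 (exact p = 0.53125) and were below 0 in leukemias 3 (-0.17) and 4 (-0.11). Replication histone genes (59) differed by 0.31 ± 0.27 (exact p = 0.0625), with 0.33, 0.69 and 0.51 in leukemias 2, 5 and 6 and 0.06, -0.04 and 0.29 in leukemias 1, 3 and 4.

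Gene models over satellite repeats (11, such as Gm10801 and Gm26870) summed to 318 to 3535 FPKM in VEH and 2916 to 15887 FPKM in DEX, a log2 difference of 2.61 ± 1.63 (SD, n = 6; exact sign-flip p = 0.03125) that was above 0 in 6 of 6 leukemias and 5.58 in leukemia 4. Olfactory and vomeronasal receptor genes (1628), which are silent in most tissues, differed by 0.14 ± 0.34 (exact p = 0.3125). Across genes, the responses of pairs of leukemias were correlated at 0.152 (leukemias 3 and 6) to 0.589 (leukemias 2 and 6), with a median of 0.403, and genes are not independent replicates there.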
